A study of Mus musculus with 2 samples.

How the data were processed

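KMT2D was profiled by ChIP-seq in wild-type HT22 cells, with 1 library precipitated with an anti-KMT2D antibody and 1 input library, both from cells at 70% confluency. Per the labels' protocols, sonicated nuclear lysates were precleared before precipitation, and libraries were made with an NEBNext Ultra II kit. The submitters' processing notes name Bowtie2, Picard and MACS2 and the build mm10; versions, settings and thresholds are not given in the sources used here. The deposited data are 1 peak list that the authors made from the ChIP and the input library. The list gives for each peak its interval, its summit, the fold or ratio of ChIP to background at the summit, the −log10 of a p-value and of a q-value, and a score. The fold values come from the authors' peak caller, MACS2 being the caller named in the submitters' processing notes, and set the ChIP pileup against a background taken from the input. The deposited score is 10 times the −log10 q cut to a whole number and was not used further. The lowest −log10 q in the deposited list was 1.32. Positions are given counted from 1, on mm10.

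Depth was read from the peak list. In MACS2 the fold is (n + 1) divided by (b + 1), and the p-value is the Poisson chance of more than n fragments with mean b, where n is the ChIP pileup and b the background. Solving both for each peak gave whole pileups whose −log10 p differed from the deposited one by less than 0.001 for 3694 of 3738 peaks (98.8%). Backgrounds below 40 were whole multiples of 0.432 in a window of 203 bp, of the matching unit in 1 kb or 10 kb, or a genome-wide floor of 2.19, for all 3639 such solved peaks. A multiple counted as whole within 1% of the unit (2% in 10 kb), and the floor within 0.0001 fragments; after moving each background at random by up to 1 unit of 0.432, 262 of the 3639 (7.20%) still met this rule. This gives a fragment length of 203 bp and an input 2.31 times as deep as the ChIP. If the preset mouse genome size of the caller was used, the libraries held about 20.2 M ChIP and 46.7 M input reads. Pileups above 406 fragments, which 63 peaks had, exceed what 1 read per position and strand allows, so duplicate positions were counted unless reads were paired. Intervals on a fold are exact 95% Poisson intervals of the pileup with the background held fixed, so they cover counting error only.

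Gene positions came from a RefSeq gene table of GRCm38.p6, the same build as mm10, with 49595 of its 49997 genes kept because they lie on the main sequence of a chromosome; 21774 are protein-coding. Strand and genome sequence were not used here. The planned distance to a transcription start was therefore replaced by the distance to the nearer end of a protein-coding gene, with 2 kb as the window. The planned CpG island counts, motif counts and background matched on promoter CpG content were not run, and the planned background without that matching became the main one. Random placements (1000) kept the number of summits per chromosome and drew positions evenly between the first and the last gene. The 47 gene lists (1508 entries, 5 unmatched) were fixed before the data were examined, like the windows, the thresholds and the rule for named genes. Each list was set against 10000 random lists of the same size. The tail share is the part of random lists as far out, on 2 sides, adjusted by Benjamini-Hochberg over the 47 lists, with a threshold of 0.05; it describes this library and is not a p-value across replicates. Medians and their ratios have bootstrap 95% intervals over peaks (1000 resamples), shares have Wilson intervals, and a share of 0 has an upper limit of 3 counts of the total.

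Named genes followed 1 rule: Kmt2d and the H3K4 methyltransferase list; the 20 gene-end peaks and the 5 other peaks of highest fold, named by the nearest gene; up to 4 members of highest fold in each called list; and the same for the oxygen, neuronal and progenitor lists. Some genes that this rule takes are not reported here. The tRNA and other small RNA genes, the X chromosome segments and genes named in the closing section outside these were chosen after their values were seen. The procedures were tested on simulated data for the same comparison: pileups were recovered for 100.0% of 2000 simulated peaks, with 20% of summits planted at gene ends 24.9% were found there, against 6.25% without planting, which gives back a planted share of 19.9% after allowing for the random share, and 165 of 200 lists planted at 30% of members among 21774 genes were called (82.5%), with 0 of 940 called where nothing was planted. Simulated hits were independent between genes, while neighbouring genes in the data could share a peak, so 0 of 940 is not their rate of false calls. Lists planted below 30% were not simulated, though several called lists had lower shares. Alternatives were stricter peak thresholds, windows of 1 kb and 5 kb, the whole peak interval in place of the summit, other backgrounds, and peaks left out. Their effects are in the closing section, apart from that of the whole peak interval, which is not reported here. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with random seed 20.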

Results

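The series profiled where KMT2D, a histone H3 lysine 4 methyltransferase, sat on chromatin in HT22 cells, an immortalised mouse hippocampal line. Wild-type cells were harvested at 70% confluency, and 1 library of chromatin precipitated with an anti-KMT2D antibody was set against 1 library of input chromatin. The series also describes cells lacking the catalytic SET domain of KMT2D, which are not analysed here. The comparison available was therefore ChIP against input in wild-type cells, as a list of peaks on the mouse genome build mm10. With 1 library of each kind there was no replicate check, and every interval below covers counting error or sampling of peaks only. Fold values are the authors', given by their peak caller for the summit of each peak, and are used only within this list. The list held 3738 peaks with a median width of 296 bp (interquartile range 242 to 405), of which 3706 lay on chromosomes 1 to 19, X and Y. The median fold over background was 4.45 (interquartile range 3.5 to 5.75; full range 1.07 to 23.5). The deposited fold and p-value of a peak together fix the fragments behind it. The median summit carried 31 ChIP fragments (interquartile range 24 to 42) over a background of 6.05 (4.32 to 8.22), and the input was 2.31 times as deeply sequenced as the ChIP.

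To ask where the KMT2D peaks lay, each summit was placed relative to protein-coding genes. Gene ends were the favoured places: 1006 of 3706 peaks, 27.1% (Wilson 95% interval 25.7 to 28.6), had their summit within 2 kb of an end of a protein-coding gene. In 1000 random placements of the same number of summits per chromosome the mean was 6.14% and the highest 7.39%, so the observed share was 4.42 times the random one. The share was 18.3% among peaks at or above the median −log10 q and 14.0% among those with fold at or above the 75th percentile of the list. Gene bodies held 1213 peaks (32.7%, against 37.9% at random) and intergenic sequence 1487 (40.1%, against 56.0%). Strand was not used here, so an end is either the start or the finish of a gene. Summits piled up closely, with 372 within 200 bp and 628 within 500 bp of an end. Their median position was 75 bp inside the gene (bootstrap 95% interval 50 to 98.5), and 58.1% were inside. Among the peaks with fold at or above the 75th percentile of the list the median turned to the outside, at -145 bp, and among those at or above the median −log10 q to -56 bp. In all, 1107 of 21774 protein-coding genes (5.08%, Wilson 95% interval 4.80 to 5.38) had a peak at an end.

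**Figure D1:**
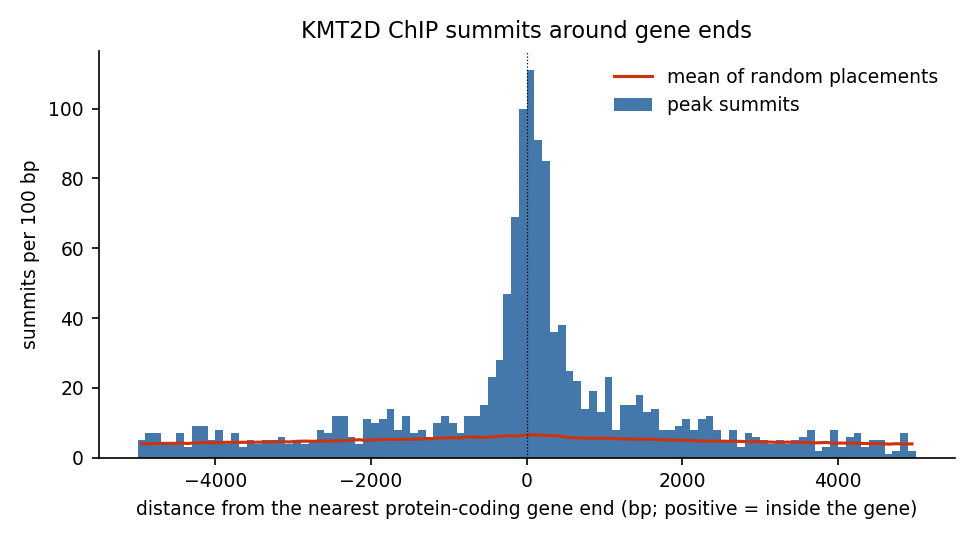
Number of peak summits (bars, per 100 bp) by distance from the nearest end of a protein-coding gene in bp, with positive distances inside the gene; the line is the mean of 1000 random placements. Summits concentrate within 500 bp of gene ends, where 628 of the 3706 peaks lie.

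Peaks at gene ends were weaker than those elsewhere. Their median fold was 3.72 against 4.73 for all other peaks, a ratio of 0.787 (bootstrap 95% interval 0.760 to 0.803). The ChIP pileups were close, with medians of 29 fragments at gene ends, 30 in gene bodies and 32 in intergenic sequence, while the background at gene ends was higher (7.35, against 5.62 and 5.71).

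**Figure D2:**
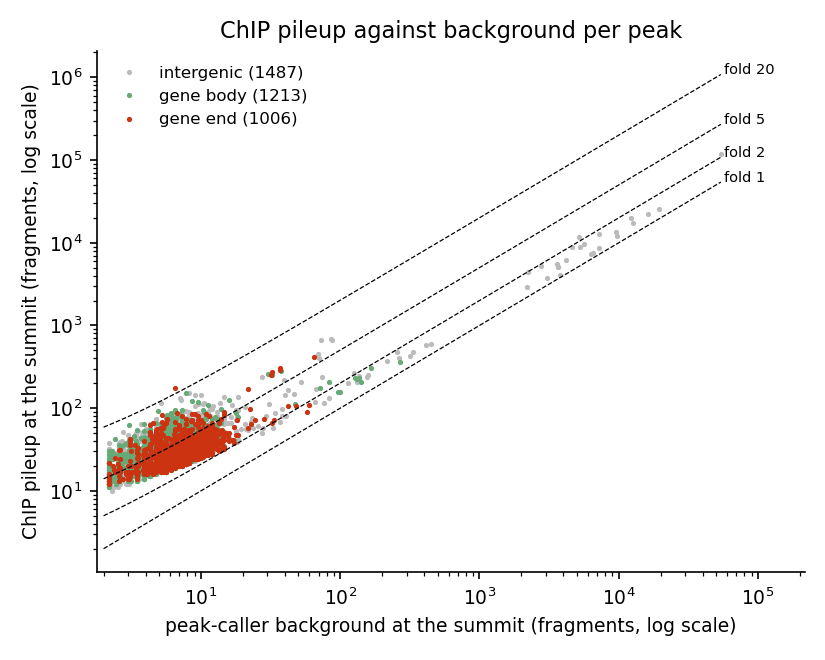
ChIP fragments at each of the 3706 placed summits (vertical, log scale) against the background of the peak caller there (horizontal, fragments, log scale), coloured by place; dashed lines mark equal fold. Gene-end peaks lie mostly between fold 2 and 5, and a separate group of mainly intergenic peaks with far higher backgrounds lies near fold 2 or below.

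The strongest gene-end peak of the list lay at Kmt2a, which encodes another H3K4 methyltransferase. It spanned chromosome 9: 44881270 to 44881793, with its summit 88 bp outside the gene, a fold of 23.5 (95% Poisson interval 20.2 to 27.2) and 175 ChIP fragments over a background of 6.49. The other 19 of the 20 highest gene-end peaks had folds from 9.35 to 13.2. Of these 20, 10 had a tRNA gene nearer to the summit than the protein-coding gene, at 13 to 38 bp. Those included the peaks beside Arl5c, Agbl5, Ilf2, Tmpo, Psma3, Aloxe3, Rnase4, Trim41 and Ctc1, with folds from 9.44 to 13.2. The peak beside Rps29 (9.37) lay nearest to Rn7s1, the RNA of the signal recognition particle. The peaks with no such gene nearest included Adamtsl4 (12.2, interval 9.51 to 15.5), Gm12447 (12.02), Ankrd40 (10.7), Rnf44 (10.1) and Vipr1 (9.77). Plin2, which encodes a lipid droplet coat protein, had a fold of 9.82, and Angptl4, a secreted inhibitor of lipoprotein lipase, 9.35. The peak beside Ttc23l (9.78) lay nearest to the pseudogene Gm8174.

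Away from gene ends, the strongest peak lay on chromosome 9 from 106405211 to 106405594, 23516 bp from Rpl29 and 125 bp from the long non-coding RNA gene Gm46131, with a fold of 18.7 (15.5 to 22.5). Next came a peak within Npas4, an activity-regulated transcription factor gene, at chromosome 19: 4992782 to 4993252 with a fold of 17.4 (14.8 to 20.4). Ankrd1, a target of the Hippo pathway, had a peak 9549 bp outside the gene with a fold of 16.6 (13.9 to 19.6), at chromosome 19: 36129104 to 36129924. A peak 3477 bp outside Dot1l, which encodes the H3K79 methyltransferase, had a fold of 16.5 (14.0 to 19.3), at chromosome 10: 80751314 to 80752011. The fifth lay within Pcdh19, a protocadherin gene on chromosome X, from 133604326 to 133604662, with a fold of 15.9 (12.3 to 20.3).

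Genes for H3K4 methyltransferase complexes themselves held peaks more often than random lists of protein-coding genes, which were not matched on promoter CpG content. Of the 20 members, 6 had a peak at an end, where random lists of protein-coding genes averaged 1.002 (adjusted tail share 0.0047). Besides Kmt2a they were Psip1 (fold 5.12, interval 4.04 to 6.40), Kmt2d (4.62, 3.17 to 6.54), Setd1a (2.92), Paxip1 (2.88) and Kmt2c (2.47). The Kmt2d peak lay at chromosome 15: 98871558 to 98872308, within the gene and 1882 bp from its nearest end. Of the other members, Kmt2b, Setd1b, Kdm6a, Ncoa6, Pagr1a, Men1, Wdr5, Rbbp5, Ash2l, Dpy30, Wdr82, Cxxc1, Hcfc1 and Bod1l had no peak at an end. Giving each peak to the nearest gene within 100 kb ended this call (6 members, adjusted tail share 0.0885), a rule chosen after the data were seen. The call also ended among peaks at or above the median −log10 q (3 of 20 against 0.341, 0.0902) and the 75th percentile of fold (1 of 20 against 0.131). With counts this small, these lost calls do not show that the excess was gone.

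Genes that respond quickly to serum, mechanical and growth signals had some of the highest shares of KMT2D peaks among the lists. Of 34 immediate early and AP-1 genes, 12 had a peak at an end against 1.74 in random lists (adjusted tail share 0.00188). The highest folds were at Zfp36 (8.67, interval 6.44 to 11.4), which encodes an mRNA decay factor, Klf10 (7.52), Ccn2 (5.99) and Dusp4 (4.69). The Klf10 peak had a background of 21.6, above the 20 fragments used as a limit of doubt. Targets of SRF and actin signalling had 10 of 30 members with a peak against 1.54 (0.00188), led by Cnn2 (6.30), Tagln2 (5.997), Myl12a (5.95) and Myl12b (4.54), which encode actin-binding and myosin light chain proteins. YAP/TEAD targets had 8 of 26 against 1.32 (0.00313), led by Ankrd1 (6.59), Ccn2 (5.99), Asap1 (4.78) and Ajuba (3.56). Kruppel-like and SP factor genes had 7 of 26 against 1.31 (0.00403), with Klf10, Klf11 (5.14), Klf6 (4.39) and Sp3 (3.86) highest. This call ended when peaks were given to the nearest gene (0.111). Klf10, Klf6 and Klf4 count in both this list and the immediate early list, and Ccn2 in both the immediate early and the YAP/TEAD lists. Bhlhe40 counts in both the circadian and the oxygen response lists, so these calls are not independent. Circadian clock genes had 7 of 23 against 1.16 (0.00188): Nr1d2 (8.25, interval 6.17 to 10.8), Per1 (6.55), Nr1d1 (6.23) and Per2 (4.35) were highest. The Per1 summit lay 11 bp from a tRNA gene, and those of Klf10 and Sp3 lay nearer to lncRNA genes (506 and 111 bp) than to these genes (1458 and 1125 bp). Among the peaks at or above the median −log10 q, the SRF and circadian lists were the 2 of all 11 lists above random that kept their calls, and at or above the 75th percentile of fold these and the immediate early genes did. Random lists averaged few members with a peak there, so a lost call does not by itself show that an excess was gone.

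**Figure D3:**
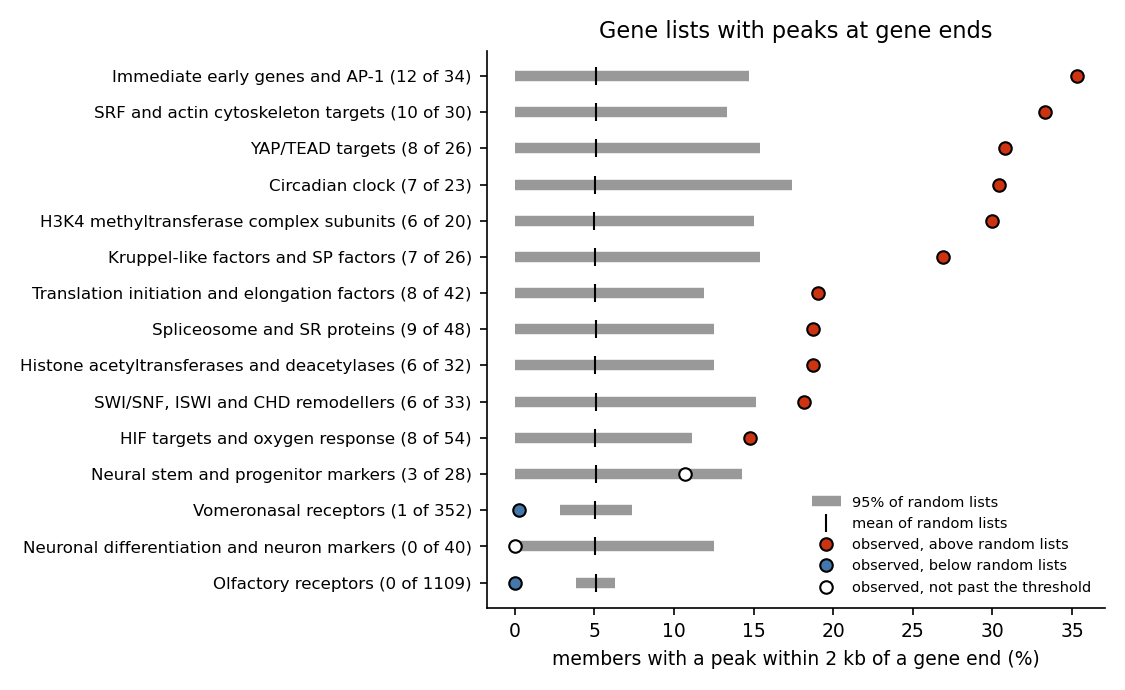
Percentage of members with a peak within 2 kb of a gene end (points) for the 13 called gene lists and both neural lists; grey bars give the central 95% of 10000 random lists and ticks their mean. All 11 lists above random lie to the right of their bars, and both receptor lists lie to the left.

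Some lists of RNA processing, translation and chromatin genes were also above random lists, and others of the same kind were not. Spliceosome and SR protein genes had 9 of 48 members with a peak against 2.45 (adjusted tail share 0.00522): U2af2 (5.04), Sf3b3 (4.99), Hnrnpk (3.94) and Hnrnpu (3.28) were highest. The Hnrnpk summit, 683 bp from that gene, lay nearer to Rmi1 (412 bp). The spliceosome call ended with a 1 kb window (0.217) and with peaks given to the nearest gene (0.605). Translation initiation and elongation factors had 8 of 42 against 2.13 (0.0132), led by Eef1a1 (5.45), Eef2 (3.74), Eif4a1 (3.67) and Eif3g (3.47). Histone acetyltransferases and deacetylases had 6 of 32 against 1.62 (0.0423), led by Kat6a (7.40, interval 5.73 to 9.42), Hdac5 (3.91), Hdac2 (3.63) and Kat5 (3.57). The Kat5 summit, 941 bp from that gene, lay nearer to Rnaseh2c (200 bp). Chromatin remodellers of the SWI/SNF, ISWI and CHD classes had 6 of 33 against 1.69 (0.0423): Smarcc2 (6.75), Arid1a (3.54), Chd3 (3.01) and Bcl7a (2.96). The Chd3 summit (862 bp) lay nearer to a lncRNA gene (353 bp). The Smarcc2 summit lay 36 bp from a tRNA gene, and without peaks at small RNA genes the remodeller list lost its call (0.14), as it did with a 1 kb window (0.0651). With peaks given to the nearest gene, the acetylation list (0.171) and the remodellers (0.324) were not past the threshold. Polycomb subunits (2 of 32), H3K4 demethylases and readers (1 of 20), cytosolic ribosomal proteins (5 of 79), mitochondrial ribosomal proteins (6 of 73) and aminoacyl-tRNA synthetases (3 of 20) were not called (adjusted tail shares 1, 1, 0.967, 0.562 and 0.333).

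Replication-dependent histone genes had 8 of 67 members with a peak against 3.41 in random lists (adjusted tail share 0.128), and neighbouring members such as H4c1 and H3c1 shared a peak. The list passed the threshold with windows of 1 kb (8 against 2.63, 0.0453) and 5 kb (13 against 4.74, 0.0103), and against random lists matched on gene length (8 against 0.88, 0.00157), a background chosen after the data were seen. It did not pass with the curated background (0.212), with peaks given to the nearest gene (0.171), in either stricter peak list (1 and 0.974), or without peaks of high background or at small RNA genes (0.117 and 0.113).

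Genes of the oxygen response, a list built around targets of the hypoxia-inducible factors, had 8 of 54 members with a peak against 2.74 in random lists (adjusted tail share 0.0456). The highest were Ccng2 (4.96, interval 3.48 to 6.88), Bhlhe40 (4.35), the glycolytic enzyme gene Aldoa (4.12) and the histone demethylase gene Kdm3a (3.94). Against 19541 genes with a curated mRNA outside the chemosensory receptors, a background chosen after the data were seen, the oxygen list (0.0761), the remodellers (0.0738) and the acetylation list (0.0738) lost their calls, and the other 8 lists above random kept theirs. Random lists matched on gene length, also chosen afterwards, ended the same 3 calls (0.0745, 0.0745 and 0.0681). The oxygen list also lost its call with a 1 kb window (0.3) and in both stricter peak lists (0.419 and 1). It kept the call with a 5 kb window (12 of 54 against 3.82, 0.00806), with peaks given to the nearest gene (15 of 54 against 7.02, 0.024) and without peaks of high background or at small RNA genes (0.0383 and 0.0376).

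Neuronal and progenitor genes did not stand apart from random lists. None of 40 neuronal differentiation and neuron marker genes had a peak at an end, where random lists averaged 2.02 (adjusted tail share 0.462). A count of 0 in 40 allows a share of up to 7.5%, so a deficit from the 5.08% of all genes was not detectable with this list. Neural stem and progenitor markers had 3 of 28 against 1.43 (0.562), among them Vim (7.33, interval 5.35 to 9.82) and Sox9 (3.07). Chemosensory receptors were nearly empty: 0 of 1109 olfactory receptor genes, which allows a share of up to 0.271%, against 56.4 in random lists (0.00188), and 1 of 352 vomeronasal receptor genes, Vmn1r43 (7.45, summit 1998 bp from the gene), against 17.8 (0.00188). Random lists matched on gene length, chosen after the data were seen, averaged 17.2 and 10.2, and both calls held (0.00157 and 0.00403). The vomeronasal call ended in both stricter peak lists (0.192 and 1). Of all 47 lists, 11 lay above and 2 below random lists, and 34 did not pass.

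The X chromosome carried 54 peaks, 1.46% of the total (Wilson 95% interval 1.12 to 1.90), while holding 4.42% of protein-coding genes, a ratio of 0.329 (0.253 to 0.429). Of these 54 peaks, 14 had their summits at or beyond position 162760157, at genes including Rbbp7, Ctps2, Zrsr2 and Mid1, and had backgrounds from 13.8 to 59.7 fragments, against 2.19 to 6.49 for the other 40. The median background of those 40 was 3.20, against 6.05 on the autosomes other than chromosome 15. Whether the number of copies of X lowered its count of peaks was not tested. Chromosome 15 had the most peaks per 100 protein-coding genes among the autosomes, 33.2, followed by chromosome 11 with 23.0. Per Mb, chromosome 11 had more, 3.10 against 2.55.

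**Figure D4:**
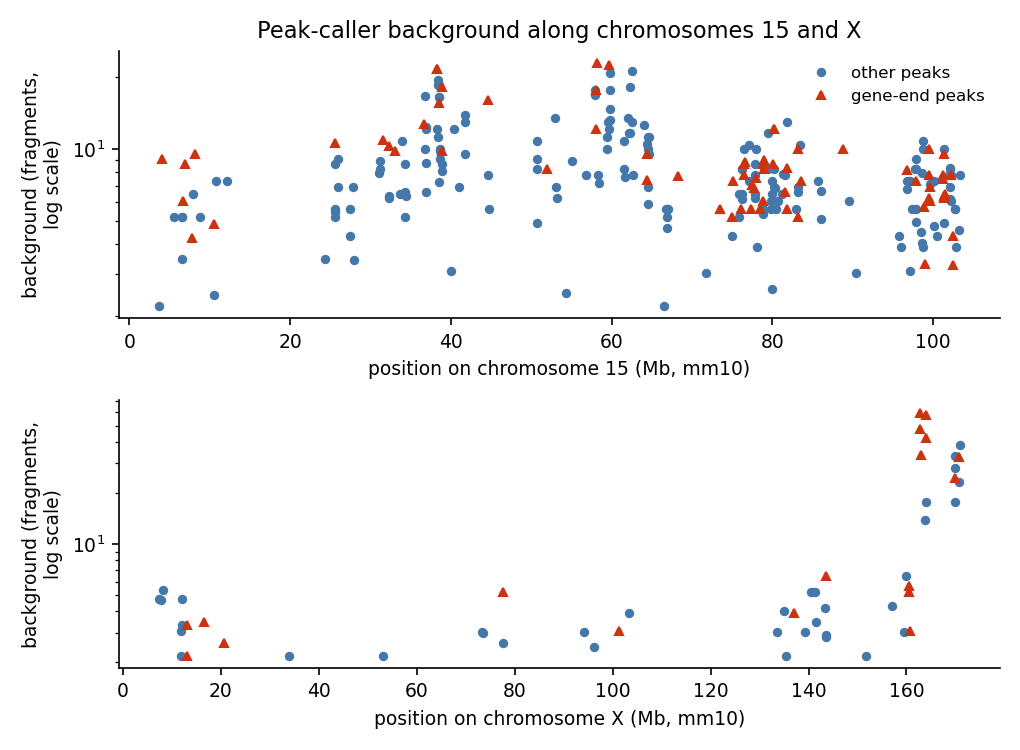
Background of the peak caller at each peak (fragments, log scale) by position in Mb along chromosomes 15 and X; triangles are gene-end peaks and circles other peaks. On X the 40 peaks with summits up to position 160766133 stay between 2.19 and 6.49, and the 14 beyond it lie between 13.8 and 59.7.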

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

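The tests of chromosome 15 outside 30 to 65 Mb and of the X segment were chosen after the result was seen; the other tests of this part were written beforehand. Outside every comparison by position, 32 peaks lay on unplaced or random sequences, with a signal above input: their folds ran from 1.13 to 2.95, and 28 of them lay on a single unplaced sequence.

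Peaks gathered at tRNA genes and at other small RNA genes: 106 summits lay within 500 bp of a tRNA gene, where random placements averaged 0.602 and reached at most 4, and 136 of 403 tRNA genes (33.7%, Wilson 95% interval 29.3 to 38.5) had one. Their median fold was 7.56, against 4.41 for the other peaks. Genes annotated as ribosomal RNA had 13 summits against 0.106 at random, at 13 of 62 genes (21.0%, Wilson 95% interval 12.7 to 32.6), with a median fold of 4.34. Most of these 13 genes are named as 5S RNA genes, and they include Rn4.5s, in the chromosome 6 array described below. Summits also lay at 2 of 3 scRNA genes, at Rpph1 and Rmrp, and 21 lay at snRNA genes and 12 at miRNA genes against 1.66 and 1.76 at random, while snoRNA genes had 3 against 2.09. The shares of snRNA, miRNA and snoRNA genes with a summit, 2.01% (1.30 to 3.08), 0.977% (0.560 to 1.70) and 0.226% (0.0767 to 0.661), were far below that of tRNA genes. Reads gathered from copies of a sequence that the build lacks would raise the background at tRNA genes. Among called summits the median background there was 0.943 times that of other summits (bootstrap 95% interval 0.857 to 1.03), so no such rise was seen at these 106 summits. Reads shared among copies that the build does hold need not raise the background. How such reads were handled is not given, so this comparison does not decide on multi-copy reads. The tRNA genes without a summit were not examined. The 13 ribosomal RNA summits had a median background of 8.22 fragments, against 6.05 at summits not at tRNA genes. Reads of multi-copy sequence stay open as a source for them too. A cause acting on every heavily transcribed gene alike is argued against by cytosolic ribosomal protein genes, of which 5.06% (Wilson 95% interval 1.99 to 12.3) had a summit within 500 bp of an end. Precipitation limited to heavily transcribed small RNA genes stays open: the interval of the ribosomal RNA share overlaps that of tRNA genes and those of snRNA, miRNA and snoRNA genes do not, but which members of these classes are heavily transcribed was not measured. Antibody binding to another protein of small RNA genes was not tested, and the design gives no biological explanation that was tested.

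Chromosome 15 had an excess of peaks for its genes, 33.2 per 100 protein-coding genes against 23.0 on the next autosome, chromosome 11. By length it was not the highest, with 2.55 peaks per Mb against 3.10 on chromosome 11. Clusters of summits within 10 kb of each other are argued against as the cause, since joining summits within 10 kb left 27.0 loci per 100 genes, against 17.9 on the next autosome. Gathering of peaks over longer stretches is not covered by this test. Extra copies of the chromosome are a candidate explanation: the median background was 1.25 times that of the other autosomes (bootstrap 95% interval 1.21 to 1.32), though chromosome 11 alone reached 7.36 against 7.55 fragments on 15. The rise was regional, at 1.70 times (1.57 to 1.90) and 72.0 peaks per 100 genes between 30 and 65 Mb. The bounds of this region were chosen after the result was seen, so the ratios inside and outside it are not independent measures. Outside that region 25.2 peaks per 100 genes remained and the ratio was 1.071 (1.01 to 1.16), which leaves extra copies open there. No biological explanation was tested.

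On chromosome X, the 7 peaks with summits from 162760157 to 164013542, at Rbbp7, Ctps2, Ap1s2, Zrsr2 and Car5b, had a median background of 42.4 fragments against 3.20 for the 40 peaks up to position 160766133. Extra copies of this segment are a candidate explanation. The lowest background over 2 kb from a gene end was 2.13 times the highest such background on the rest of X. That value rests on 2 summits in the segment and 29 outside. The bounds of the segment were drawn after these backgrounds were seen, so a high ratio was to be had in advance and does not test the explanation. The 7 peaks with summits from position 169989729 on, near the part that X shares with Y, had a median background of 28.1. No biological explanation was tested.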

How the results depend on the processing

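No paired analysis was possible because each group holds 1 library. The CpG island, motif, CpG-matched and single-start alternatives were not run. Alternatives that leave out peaks of high background or at small RNA genes, and those with curated, length-matched or nearest-gene backgrounds, were chosen after the data were seen. Fewer peaks enter the stricter lists, so counts fall by construction; for other shifts the cause was not tested. At or above the median −log10 q, 1870 peaks remained, with 18.3% at gene ends, 374 genes, a fold ratio of 0.902, a median summit at -56 bp, and 2 lists above and 1 below random. At or above the 75th percentile of fold, 935 peaks remained, with 14.0% at gene ends, 143 genes, a fold ratio of 1.02 (uninformative, as the list is selected on fold), a median summit at -145 bp, and 3 lists above and 1 below. The oxygen, translation and spliceosome lists had 0 members with a peak there, a ratio to random of 0. Random lists averaged only 0.353, 0.273 and 0.317 members for them, so these counts of 0 say little. Windows of 1 kb and 5 kb gave 21.0% and 36.7% at gene ends (3.26% and 13.4% at random), and 5 kb a fold ratio of 0.821. By chromosome length the X ratio was 0.231. The curated background removed both receptor lists and left 0 below. Lists above random numbered 8 to 14 under the other 7 alternatives, and of the 13 calls 3 held under each alternative run on them: SRF targets, circadian clock and olfactory receptors. The stated depth limits weak peaks: the lowest pileup called was 10 fragments.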

Other observations

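The assignment of peaks to genes in this part was chosen after the data were seen. When each peak was given to the gene with the nearest end within 100 kb, and random lists were matched on the number of randomly placed summits a gene receives, mesenchymal and extracellular matrix genes carried peaks in 20 of 38 members against 5.62 in random lists (adjusted tail share 0.00157). The highest folds were near Bgn (12.1, 95% Poisson interval 8.92 to 15.9), Col1a2 (10.1), Timp2 (9.66) and Col6a1 (8.51), which encode matrix proteins and an inhibitor of matrix proteases. Within 2 kb of gene ends the same list had 5 of 38 members with a peak and was not past the threshold (0.216). TGF-beta and BMP signalling genes had 12 of 35 against 5.16 (0.0316), led by Tgfbr2 (10.3), Tgfbr3 (9.22) and Smurf1 (7.81), and heat shock genes 7 of 20 against 1.83 (0.024). Within 2 kb of gene ends these were not past the threshold either, with 5 of 35 (0.17) and 4 of 20 (0.112). Immediate early genes reached 22 of 34 against 4.24 (0.00157), with Npas4, Ier5 (12.9) and Dusp1 (9.22) highest. Neuron markers had 2 of 40 against 6.30 (0.171), Cux1 and Nrp1.

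Several genes had many peaks around them. They were picked as high counts among all genes, so the random means beside them do not show how unusual they are. Gm52481 on chromosome Y had the most, 9, where random placement gave 0.026. These were all the peaks on Y and formed 2 loci when summits within 10 kb were joined. Their median fold was 2.53, and their median background of 21.6 was above the 20 fragments used as a limit of doubt. Irf2bp2 and Socs3, a feedback inhibitor of cytokine signalling, had 8 peaks each, where random placement gave 0.29 and 0.166. Irf2bpl had 7 peaks (random 0.099), Zfp36l2 7 (0.263), and Cebpb, a transcription factor gene, 6 (0.144). Gm40363 (0.104), Azin1 (0.516) and Gas8 (0.117) also had 7 each. The highest fold near Gm40363, 9.07, was also the highest in the chromosome 6 array around Rn4.5s described below. The Gm40363 count therefore includes at least that array peak.

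On chromosome 6, 17 peaks lay between 47650652 and 47772331 with a median spacing of 4330 bp, at and around Rn4.5s, which encodes a small rodent RNA. Their pileups ran from 113 to 688 fragments and their folds from 1.505 to 9.07. The peak with the highest −log10 q, 12402, lay on chromosome 2 from 98666411 to 98667457 and had 118678 ChIP fragments over a background of 54170 and a fold of 2.19. In all, 81 of 3738 peaks had a fold below 2, and 30 of these lay on unplaced sequences.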
